A study of Mus musculus with 2 samples.

How the data were processed

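The material was nuclei from hippocampi of C57BL/6J mice at 6 weeks of age, pooled from 3 mice per group into 1 AAV-STOP and 1 AAV-TAU library and sequenced as 10x Genomics 3' libraries, with about 20000 nuclei loaded per sample. The deposited matrices hold counts of UMIs per gene and filtered barcode, made by the authors with Cell Ranger on the mm10 mouse genome. The matrix headers name Cell Ranger 8.0.1, while the submitters' notes name Cell Ranger 4.0 and Seurat 4.4.0. Each matrix had 32285 mouse genes and no transgene. No deposited table of cell types was among the files used, so cell classes were rebuilt from the counts. Gene identifiers were matched to GENCODE vM21 (GRCm38), in which 220 of 220 named identifiers were found. Mouse Mapt does not check which library received which vector, since both vectors carry a human MAPT transcript.

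All steps used Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Nuclei were kept with 500 or more UMIs, 300 or more genes and at most 5% mitochondrial UMIs. No barcode fell below the first pair of limits, and the mitochondrial limit removed 4 AAV-STOP and 2 AAV-TAU barcodes. Doublets were marked per library with the scrublet method of scanpy (expected rate 0.15) and left out: 2608 AAV-STOP barcodes (12.9%) and 2252 AAV-TAU barcodes (11.5%). The 34995 nuclei left were scaled to 10000 counts each and log transformed. They were clustered jointly without integration on 3000 variable genes, 30 principal components and 15 neighbours, by the leiden method at resolution 1. A cluster took the name of the marker set with the highest mean log2 level over the median of all clusters. The marker sets, filters, list method, named-gene rule, gene lists and main alternatives were fixed before the data were examined. The thresholds of naming were set after seeing the data: a mean of at least 1.6, a lead of at least 0.3 over the next type, at least 3 markers raised over 2 times at 10 CPM or more, and no more markers of another type than its own among its 10 leading genes. A cluster of glial or vascular type whose Rbfox3 level passed 50% of the median of neuronal clusters was left without a name. A class is called like a cell type because it rests on marker genes alone. The naming thresholds, and the tests of technical explanations, were set after seeing an earlier computation of the same steps on the same data with other processor instructions. It marked a few AAV-STOP barcodes differently, and CA2-like, border macrophage-like and choroid plexus-like classes formed in it that did not form in the computation reported, while an endothelial-like class did not. The fixed set of instructions was kept because it repeats exactly, and which small classes form depends on such small differences.

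Counts were summed over the nuclei of a class in each library and given as CPM, the counts of a gene per 1000000 counts of the class. Ratios are log2((CPM in AAV-TAU + 5)/(CPM in AAV-STOP + 5)). With 1 library per group no test, p-value or standard error was computed. Summed counts carry exact 95% Poisson intervals, ratios of counts the matching exact intervals, and shares of nuclei exact (Clopper-Pearson) 95% binomial intervals. These cover counting error only and not the spread between mice. At 20 CPM the interval was 18.2 to 21.9 CPM in granule-like neurons of AAV-TAU and 8.04 to 41.2 CPM in microglia-like nuclei of AAV-STOP, the thinnest of the 7 main classes. Where a share was 0, its upper limit was taken as 3 counts of the total. Classes were compared for gene levels with 100 or more nuclei in both libraries, which left 13 classes.

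Genes were named by a fixed rule of size. Among genes with 100 or more UMIs and 20 CPM or more in the library with the higher level, the 6 highest and the 6 lowest ratios per class were taken, then Mapt, then up to 3 members of each list read in that class with the largest absolute ratio. Gene models named Gm or Rik, mitochondrial, ribosomal protein and haemoglobin genes, Xist, Tsix, the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, and markers of other classes, were left out of the highest and lowest. Other X-linked genes, such as Mid1 and Arhgap6, stayed in. Not every gene that the rule names is printed, and 2 genes that it names were left out of the reported gene values with no other gene put in their place. The 24 gene lists covered immediate early genes, axon injury and neuronal stress, glutamatergic and GABAergic synapses, microtubule and tau related genes, the unfolded protein response, heat shock, p53 targets, the interferon response, MHC class I and II, disease associated and homeostatic microglia, complement, cytokines and chemokines, lysosome and phagocytosis, reactive and homeostatic astrocytes, disease associated oligodendrocytes, myelin, cholesterol synthesis, the nuclear respiratory chain, Alzheimer risk and tau genes, and voltage gated channels. A list's value is the median log2 ratio of its members at 5 CPM or more in at least 1 library, given for at least 3 such members. Its percentile is that among 10000 random lists of the same size matched on mean expression, and it describes these 2 libraries and is no p-value. Lists matched on expression and gene length were added after seeing the data, as were lists of glucocorticoid-induced and clock genes.

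The list method was tested on simulated data made from the granule-like counts of 10985 genes. It placed 20 of 20 raised lists above and 20 of 20 lowered lists below the central 95% of random lists, and 1 of 100 lists without a difference outside it. The changed genes had median log2 ratios of 0.87 and -0.86, larger than the list medians reported here, and only counting noise was simulated. The simulation therefore does not show how the method does at the sizes reported. The alternatives fixed beforehand were marked doublets kept, the 15% of highest doublet score left out, a floor of 1000 UMIs, clustering at resolutions 0.5 and 2, genes centred within each library, clustering without the response lists, scaling by the median of ratios, a pseudocount of 1, means over nuclei, nuclei thinned to 1000 UMIs, 10% of assumed free RNA subtracted, and list members with any UMI or with 20 CPM or more. Chosen after seeing the data were floors of 2000 and 2500 UMIs, counting in the mixed cluster of macrophage and microglial genes, another clustering seed, nuclei matched on mitochondrial share, and the clusters of resolution 2 inside the granule-like and oligodendrocyte-like classes and among the mixed nuclei. Since every nucleus held over 1000 UMIs, thinning to equal depth differs from means over nuclei only by the draw of fewer counts. Genes left out of every comparison and clusters of no class were not analysed for gene levels.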

Results

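Single-nucleus RNA sequencing was done on hippocampi of C57BL/6J mice at 6 weeks of age. The mice had received adeno-associated virus (AAV) into both lateral spaces of the brain at postnatal day 0. In the control group (AAV-STOP) the vector carried a human MAPT transcript with an early stop codon, so that no tau protein was made. In the other group (AAV-TAU) it carried full-length wild-type human tau of the 2N4R form. The hippocampi of 3 mice per group were pooled into 1 library per group, so each group has 1 value, no test was possible and no spread between animals is known. The AAV-STOP library held 20265 barcodes and 130252240 UMIs, with a median of 5750 UMIs per barcode. The AAV-TAU library held 19596 barcodes and 109428807 UMIs, with a median of 5119. After filtering, 17653 AAV-STOP and 17342 AAV-TAU nuclei were kept, with medians of 5585 and 4953 UMIs and of 2497 and 2399 genes. The series text mentions a further form of the vector, which was not analysed here. The comparison asks which cell classes and genes of the hippocampus differ in level when wild-type human tau is expressed.

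The libraries were alike in several features of their make-up. Malat1, a nuclear non-coding RNA, took 8.99% of the UMIs in AAV-STOP and 8.59% in AAV-TAU, and the 100 most abundant genes took 29.5% and 28.0%. Xist, transcribed from the inactive X chromosome, stood at 8.93 and 6.84 CPM (UMIs of a gene per 1000000 UMIs), and the Y-linked gene Eif2s3y stood at 172 and 162 CPM. Ttr, abundant in choroid plexus, stood at 84.2 CPM in AAV-STOP and at 109.7 CPM in AAV-TAU. The median mitochondrial share per nucleus was 0.172% in AAV-STOP and 0.280% in AAV-TAU. The gene list of the files held no human MAPT, so the transgene itself could not be followed. Mouse Mapt (ENSMUSG00000018411, chromosome 11, 104231390 to 104332090 in mm10), the endogenous tau gene, was alike between the libraries in most classes. In dentate granule-like neurons it stood at 237 CPM (95% Poisson interval 232 to 243) in AAV-STOP and at 244 CPM (238 to 251) in AAV-TAU. The interval of the ratio included 1 in 11 of 13 classes. It lay above 1 in CA1-like neurons (229.9 against 254 CPM, ratio 1.11, 1.06 to 1.16) and below 1 in oligodendrocyte-like nuclei (1500.5 against 1380.4 CPM, ratio 0.920, 0.889 to 0.953). All Poisson and binomial intervals cover counting error only.

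Joint clustering gave 34 clusters, of which 23 were named from marker genes as 15 classes. Dentate granule-like neurons were the largest class, and they and CA1-like neurons held a smaller share in AAV-TAU, while oligodendrocyte-like, astrocyte-like and microglia-like nuclei held a larger one. Granule-like neurons made up 29.6% of AAV-STOP nuclei (95% binomial interval 28.9 to 30.2) and 24.2% of AAV-TAU nuclei (23.5 to 24.8), a log2 ratio of -0.29 that was -0.16 with 2000 or more UMIs asked of both libraries. CA1-like neurons made up 12.7% and 11.2%, a log2 ratio of -0.18 that was -0.05 at that floor. CA3-like neurons made up 4.83% and 4.78%, and inhibitory neuron-like nuclei 7.26% and 7.63%. Oligodendrocyte-like nuclei made up 8.74% and 11.2%, and astrocyte-like nuclei 3.13% and 4.88%. At the common floor their log2 ratios were 0.15 in place of 0.36 and 0.54 in place of 0.64. The smallest barcode in the files held 1973 UMIs in AAV-STOP and 1633 in AAV-TAU, and glial nuclei held few UMIs.

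Microglia-like nuclei were 156 in AAV-STOP (0.884%, 0.751 to 1.03) and 506 in AAV-TAU (2.92%, 2.67 to 3.18), a ratio of 3.30, at medians of 2210 and 1925 UMIs. With 2000 or more UMIs asked of both libraries they were 140 (0.797%) and 188 (1.196%), a ratio of 1.50. No AAV-STOP barcode held fewer than 1973 UMIs, so this floor removed mainly AAV-TAU nuclei. A further cluster was led by macrophage and microglial genes (F13a1, Mrc1, Runx1, Inpp5d) mixed with neuronal RNA, and it was kept out of the class by a threshold set after the data were seen. It held 334 AAV-STOP nuclei (1.89%) and 99 AAV-TAU nuclei (0.571%). Microglia-like nuclei and that cluster, which holds macrophages too, together made up 2.78% and 3.49%, a ratio of 1.26, and with 2000 or more UMIs the direction turned (2.69% and 1.70%, ratio 0.631). With marked doublets kept, microglia-like and mixed microglial barcodes had a ratio of 1.10 at that floor. At resolution 2 the mixed nuclei came as a cluster of microglial genes (186 and 15 nuclei) and one of macrophage genes (148 and 78 nuclei). Microglia-like nuclei with the microglial one alone made up 1.94% and 3.00%, a ratio of 1.55, or 0.696 with 2000 or more UMIs.

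Of the smaller classes, Cajal-Retzius-like neurons held 0.685% and 0.986%, subicular or cortical-like neurons 2.86% and 3.32%, and immature neuron-like nuclei 2.84% and 2.497%. Oligodendrocyte precursor-like nuclei held 3.34% and 3.26%, newly formed oligodendrocyte-like nuclei 1.51% and 1.34%, and cycling-like nuclei 0.329% and 0.386%. Endothelial-like nuclei were 49 (0.278%, 0.205 to 0.367) and 77 (0.444%, 0.351 to 0.555), or 46 and 53 with 2000 or more UMIs, a log2 ratio of shares of 0.36 in place of 0.68. The fibroblast-like class held 1.44% and 1.45%, from cluster 25 (144 and 189 nuclei) and cluster 32 (110 and 63 nuclei), and its log2 ratio of 0.01 turned to -0.21 at that floor. Nuclei of no class made up 19.6% and 19.5%. Among them, 8 clusters with low marker levels held 15.2% and 15.9%, 2 clusters of mixed neuronal and other RNA held 2.68% and 0.923%, and 1 cluster between CA3-like and mossy cell markers held 1.74% and 2.65%. The mixed clusters were that of macrophage and microglial genes and a cluster with the choroid plexus genes Ttr and Htr2c, which held 0.787% and 0.352%. At resolution 1 no cluster was named as CA2-like, border macrophage-like or choroid plexus-like. At resolution 2 a CA2-like cluster held 146 AAV-STOP and 111 AAV-TAU nuclei, and a choroid plexus-like one 30 and 46. The CA3-like class had the CA2 markers as its next set, so it may hold CA2-like nuclei.

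**Figure D1:**
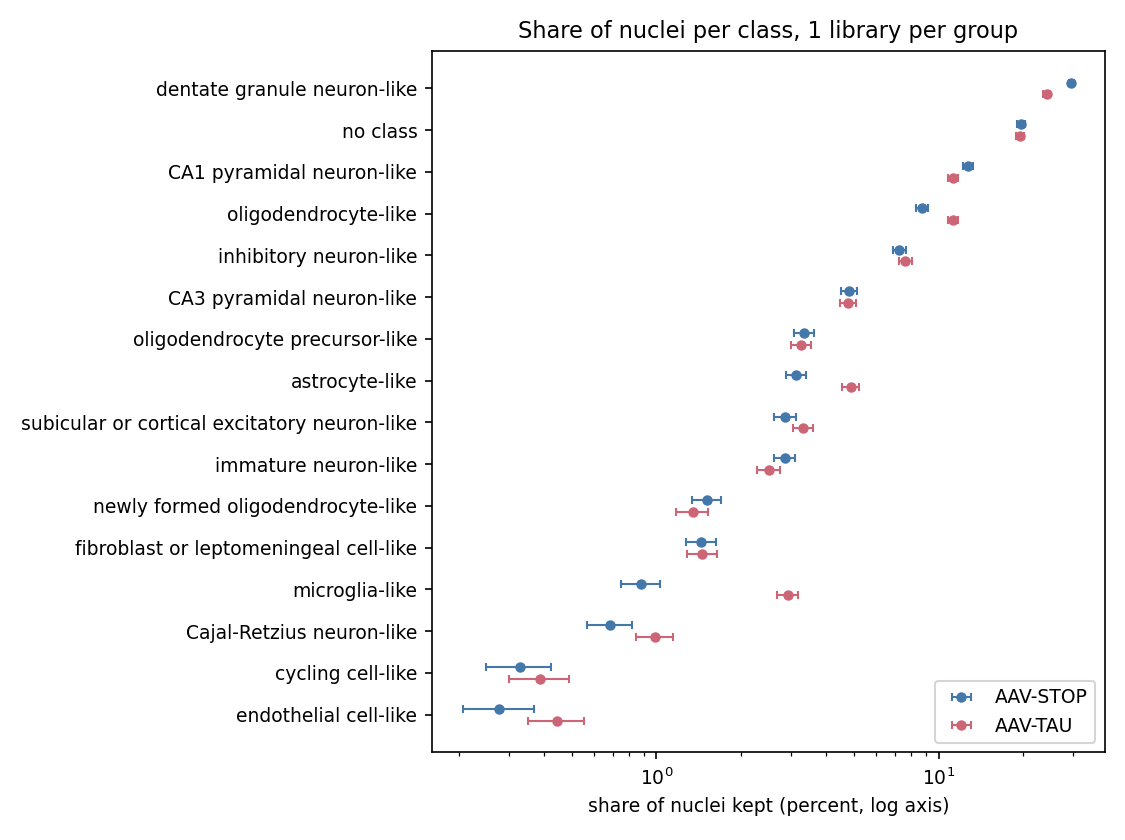
Share of the nuclei kept per class in the AAV-STOP and the AAV-TAU library (percent, log axis); points are the shares of 1 library per group and bars their exact 95% binomial intervals. The intervals of the microglia-like class (0.884% and 2.92%) lie apart, and those of the fibroblast-like class (1.44% and 1.45%) overlap.

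In dentate granule-like neurons, the genes with the largest ratios were Tmsb10, which encodes an actin-binding thymosin, and Ntm, an adhesion molecule of neurons. Tmsb10 (ENSMUSG00000079523, chromosome 6, 72957347 to 72958748) stood at 18.8 CPM in AAV-STOP (17.3 to 20.4) and at 37.6 CPM in AAV-TAU (35.1 to 40.2), and Ntm at 72.6 and 133 CPM. The glycolytic enzyme gene Gapdh was at 111 and 191 CPM, and the ubiquitin gene Ubb at 145 and 249 CPM. The genes with the lowest ratios were Maml2, a co-activator of Notch signalling (1500.5 against 1094 CPM), Mid1, a ubiquitin ligase that binds microtubules (29.0 against 19.9 CPM), Spred1 (80.4 against 60.6 CPM), Ubash3b (122 against 92.5 CPM), Tmem144 (38.5 against 28.9 CPM) and Parp8 (93.1 against 72.0 CPM). All 10 measured heat shock genes were higher in AAV-TAU, with a median log2 ratio of 0.45. The chaperone genes Hsp90aa1 (156 against 245 CPM) and Hsp90ab1 (344 against 506 CPM) led them. All 22 measured nuclear genes of the respiratory chain were higher as well (median log2 ratio 0.32), among them Cox8a (52.3 against 80.6 CPM) and Atp5g1 (31.8 against 47.6 CPM). Of 29 microtubule and tau related genes, 23 were higher (median 0.16), with the tubulin gene Tuba1a at 88.4 and 145 CPM and Stmn1 at 49.4 and 80.3 CPM. All 12 measured axon injury and neuronal stress genes were higher (median 0.26), among them Gap43, a protein of growth cones (22.8 against 37.9 CPM), Stmn2 (62.2 against 85.1 CPM) and the neurofilament gene Nefl (45.3 against 62.3 CPM). Each of these 4 medians lay at percentile 100 among 10000 random lists matched on expression. Unfolded protein response genes had a median of -0.06 with 6 of 16 higher, at percentile 0.01, and Pdia6 was at 94.1 and 79.0 CPM. Of 11 p53 targets 10 were higher (median 0.19, percentile 99.1), with Bax at 26.4 and 32.3 CPM.

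Markers of RNA quality and of other cells moved in the same class. The median mitochondrial share of granule-like nuclei was 0.169% in AAV-STOP and 0.268% in AAV-TAU. Genes under 5 kb had a median log2 ratio of 0.18, with 88.4% of 942 genes higher, and genes over 100 kb one of -0.02. With random lists matched on gene length too, the p53 median lay at percentile 96.6, inside the central 95%, and it was 0.067 over all members with a UMI. Myelin genes, which belong to oligodendrocytes, were all higher in granule-like neurons (13 of 13, median 0.23), and Cnp, one of them, was at 23.3 and 41.2 CPM. A scaling by the median of ratios set the granule-like median of the microtubule list at 0.097 and that of the unfolded protein list at -0.14, while the latter was -0.022 with nuclei thinned to equal depth. The libraries filled the class unevenly: of 6 clusters of resolution 2 with 100 or more granule-like nuclei in both libraries, cluster 8 held 1272 AAV-STOP and 442 AAV-TAU nuclei. Inside these clusters the medians were 0.35 to 0.64 for heat shock, 0.22 to 0.33 for the respiratory chain, 0.11 to 0.21 for microtubule, 0.063 to 0.32 for axon injury and -0.12 to 0.022 for unfolded protein genes.

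CA1-like neurons had higher heat shock, respiratory chain and immediate early gene levels in AAV-TAU. All 10 heat shock genes (median log2 ratio 0.43) and all 22 respiratory chain genes (median 0.30) were higher, with Hspa8 at 155 and 234 CPM. Of 16 measured immediate early genes, which respond to neuronal activity, 13 were higher, with a median of 0.21 at percentile 99.9 that was 0.05 over the members at 20 CPM or more. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) was at 21.5 CPM (19.4 to 23.8) and 34.5 CPM (31.5 to 37.6), Nr4a2 at 32.6 and 44.3 CPM and Nr4a3 at 35.6 and 43.9 CPM. Axon injury genes had a median of 0.21 (11 of 12 higher, percentile 99.9) and microtubule genes one of 0.14 (22 of 29 higher, percentile 100). Fabp5, a fatty acid binding protein, was at 13.6 and 25.7 CPM, Tuba1a at 68.2 and 115 CPM and Dbi at 13.7 and 24.4 CPM. Mid1 (22.3 against 13.3 CPM), Stac (101 against 71.1 CPM), Fbxl7 (55.0 against 40.2 CPM), Ntrk2, a receptor for neurotrophins (595 against 474 CPM), and the potassium channel gene Kcnq5 (669 against 542 CPM) were lower. The unfolded protein list had a median of -0.01 (7 of 16 higher, percentile 1.46), and its sign turned under 2 of the alternatives tried. CA1-like nuclei had median mitochondrial shares of 0.119% and 0.216%, and genes under 5 kb had a median log2 ratio of 0.18. Over 20 draws of nuclei matched on mitochondrial share the medians were 0.17 to 0.25 for the respiratory chain, 0.097 to 0.16 for axon injury and 0.050 to 0.12 for microtubule genes, and the last was 0.023 with nuclei thinned to equal depth. Lists chosen for other cell types were higher as well, with medians of 0.19 for myelin (11 of 12 higher, percentile 99.4) and 0.19 for disease associated microglia (10 of 11 higher, percentile 99.0).

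In CA3-like neurons, Sema5a, a semaphorin that guides axons, and Ttn, which encodes titin, had the lowest ratios. Sema5a (ENSMUSG00000022231, chromosome 15, 32244810 to 32696341) was at 71.8 CPM (66.3 to 77.5) in AAV-STOP and at 37.2 CPM (33.1 to 41.7) in AAV-TAU. Ttn was at 34.9 and 18.1 CPM, and Pitpnm3 at 21.3 and 12.95 CPM. Arhgap6 was at 23.4 and 11.6 CPM, but its ratio depended on how the class was drawn, with a log2 value of 0.93 at the finer clustering resolution. Gapdh (79.8 against 126 CPM), Tuba1a (63.0 against 97.01 CPM), Stmn1 (31.6 against 49.3 CPM) and Akain1 (19.7 against 32.6 CPM) were higher. All 9 measured heat shock genes were higher (median 0.39), with Hspd1 at 32.8 and 47.8 CPM, and so were 21 of 22 respiratory chain genes (median 0.25). Of 29 microtubule genes 22 were higher (median 0.12, percentile 99.9). The median was -0.06 with nuclei thinned to equal depth, a draw of fewer counts, while means over nuclei did not turn its sign. The axon injury (0.12) and immediate early gene (0.10) medians lay at percentiles 84.7 and 76.6, and Bdnf, a neurotrophin, was at 68.2 and 57.0 CPM. The unfolded protein list had a median of -0.04 (4 of 15 higher, percentile 1.91), with Atf6 at 149 and 129 CPM, and it turned sign at the coarser clustering resolution. Mitochondrial shares had medians of 0.0916% and 0.132%, and genes under 5 kb had a median log2 ratio of 0.16. With nuclei matched on that share the heat shock median was 0.23 to 0.30 and the respiratory chain median 0.12 to 0.18 over 20 draws, and heat shock stood at 0.20 over all members with a UMI. Myelin genes were higher in CA3-like neurons too (9 of 11, median 0.24, percentile 99.8).

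Inhibitory neuron-like nuclei had higher heat shock (10 of 10, median 0.46), respiratory chain (22 of 22, median 0.23) and microtubule (22 of 29, median 0.12, or 0.066 with median of ratios scaling) genes. Hsp90aa1 was at 169 and 267 CPM and Uqcr11 at 17.7 and 33.3 CPM. Hpca, a calcium sensor, was at 67.3 and 115 CPM, and Nrgn, abundant in excitatory neurons, at 144 and 234 CPM. Axon injury genes had a median of 0.20 (11 of 13 higher, percentile 99.6), with the neuropeptide gene Npy at 85.6 and 111 CPM. Immediate early genes had a median of 0.20 (8 of 11 higher, percentile 97.01), which was 0.072 with marked doublets kept, and p53 targets one of 0.20 (8 of 12 higher, percentile 98.9, or 95.3 with lists matched on gene length, and 0.075 over all members with a UMI). Unfolded protein response genes had a median of 0.04 (11 of 18 higher, percentile 37.8), with the transcription factor gene Atf4 at 18.5 and 26.0 CPM. GABAergic synapse genes had a median of -0.08 (5 of 16 higher, percentile 2.12), with the receptor subunit gene Gabrb2 at 543 and 458 CPM. Sema3a (26.5 against 16.0 CPM), Angpt1 (22.8 against 14.4 CPM) and Zfp804a (447 against 318 CPM) were lower. Inhibitory neuron-like nuclei held median mitochondrial shares of 0.211% and 0.335%, and genes under 5 kb had a median log2 ratio of 0.19.

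Synaptic and channel genes had medians slightly below 0 in the main neuronal classes, and all but the GABAergic list of inhibitory neuron-like nuclei lay inside the central 95% of random lists. Glutamatergic synapse genes had medians of -0.05 in granule-like (percentile 18.1), -0.02 in CA1-like (72.7), -0.03 in CA3-like (27.8) and -0.05 in inhibitory neuron-like nuclei (21.0), although Nrgn was higher in granule-like neurons (407 against 519 CPM) and Gria4 lower (148 against 121 CPM). GABAergic genes had medians of -0.02 in granule-like (percentile 35.0), -0.03 in CA1-like (23.1) and -0.03 in CA3-like neurons (13.1). Voltage gated channel genes had medians of -0.04 in granule-like, -0.05 in CA1-like, -0.05 in CA3-like and -0.06 in inhibitory neuron-like nuclei, at percentiles from 5.98 to 15.2, in the lower part of the random lists in each class. The median of the p53 list was 0.08 in CA1-like and 0.0052 in CA3-like neurons, and over the alternatives its lowest value was -0.0034 in the former and it ranged from -0.052 to 0.275 in the latter. The immediate early genes in granule-like neurons had a median of 0.13 (percentile 85.5), which was -0.10 over the members at 20 CPM or more. Interferon and MHC class I genes were too low in granule-like, CA1-like and CA3-like neurons for a median. In inhibitory neuron-like nuclei their medians were 0.26 (3 of 3 higher, percentile 92.2) and 0.0093 (percentile 27.9).

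**Figure D2:**
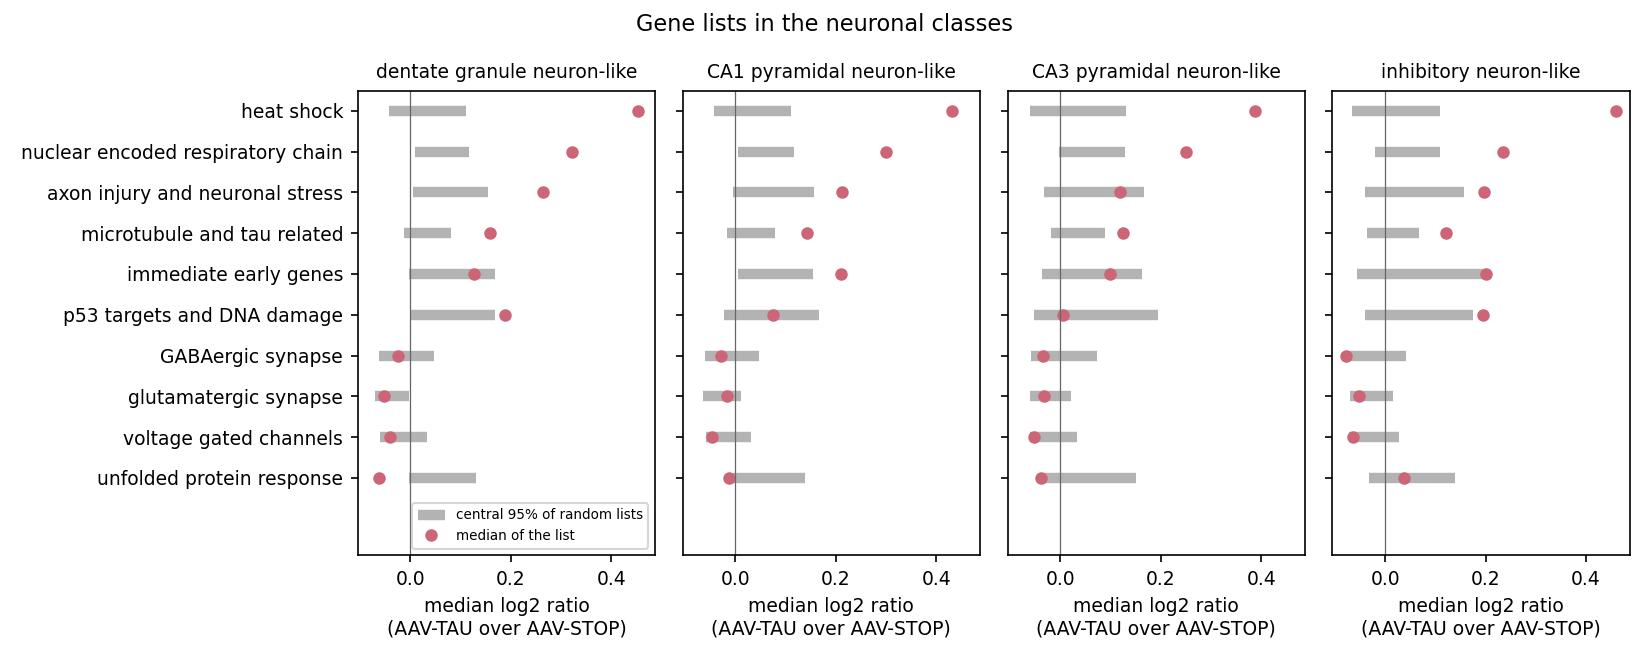
Median log2 ratio (AAV-TAU over AAV-STOP) of 10 gene lists in the granule-like, CA1-like, CA3-like and inhibitory neuron-like classes; red points are the list medians and grey bars the central 95% of random lists matched on expression. The heat shock medians, from 0.39 to 0.46, lie to the right of the grey bars in each of these classes.

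In astrocyte-like nuclei, reactive astrocyte genes were lower in AAV-TAU. Their median log2 ratio was -0.30, with 5 of 15 higher, at percentile 0.04. It was -0.11 over all members with a UMI and -0.35 to -0.13 over 20 draws of nuclei matched on mitochondrial share. Gfap, the intermediate filament gene of astrocytes (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), was at 122 CPM (105 to 141) in AAV-STOP and at 82.7 CPM (71.2 to 95.5) in AAV-TAU, and Id3 at 64.9 and 46.9 CPM. Tnc, a matrix protein gene, was at 192 and 126 CPM. With nuclei thinned to equal depth, a draw of fewer counts, its log2 ratio was 0.0021, while means over nuclei did not turn its sign. The lowest ratios were those of Afap1l2 (66.2 against 27.3 CPM), Klhl29 (84.2 against 40.2 CPM), Igfbp5 (108 against 59.4 CPM) and Nrg1 (199 against 109 CPM). The highest were those of Cacybp (32.8 against 75.5 CPM) and Slc43a2 (32.8 against 75.1 CPM). Homeostatic astrocyte genes had a median of -0.12 (3 of 15 higher, percentile 15.2, or 0.790 with lists matched on gene length), with Mertk, a receptor for phagocytosis, at 1124 and 828 CPM and the water channel gene Aqp4 at 163 and 132 CPM. Cholesterol synthesis genes had a median of 0.21 (15 of 18 higher, percentile 98.5, or 93.7 with lists matched on gene length), with Hmgcs1 at 66.2 and 87.1 CPM. Interferon genes had a median of 0.28 (8 of 11 higher, percentile 94.8) and MHC class I genes one of 0.19 (percentile 76.2). Median mitochondrial shares were 0.192% and 0.234%, and genes under 5 kb had a median of 0.21.

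In oligodendrocyte-like nuclei the lowest ratio was that of Zbtb16, a transcriptional repressor (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222). It was at 383 CPM (365 to 403) in AAV-STOP and at 144 CPM (134 to 156) in AAV-TAU, a log2 ratio of -1.38. Zbtb16 was lower also in newly formed oligodendrocyte-like (98.1 against 38.2 CPM) and oligodendrocyte precursor-like nuclei (102 against 50.8 CPM), with a log2 ratio of -0.22 in the former when marked doublets were kept. Of 3 oligodendrocyte-like clusters at resolution 2, cluster 6 held 462 AAV-STOP and 1001 AAV-TAU nuclei of the class, and inside the 3 the log2 ratio of Zbtb16 was -1.62 to -1.37. Spock1, a proteoglycan gene, was at 663 and 370.4 CPM, and Zfand4 at 68.5 and 35.8 CPM. Tmsb10 (37.6 against 82.7 CPM), Ndn (17.0 against 37.6 CPM) and the ubiquitin hydrolase gene Uchl1 (89.8 against 175 CPM) were higher. Disease associated oligodendrocyte genes had a median of -0.12 (5 of 12 higher, percentile 1.73), and Sgk3 was at 155 and 104 CPM. That median became 0.0017 with nuclei thinned to equal depth, a draw of fewer counts, while means over nuclei did not turn its sign. Myelin genes had a median of -0.09 with 5 of 14 higher (percentile 46.3, or 1.73 with lists matched on gene length), yet Cnp (224 against 272 CPM), Trf (939 against 1100.1 CPM) and Mal (974 against 1138 CPM) were higher. Cholesterol synthesis genes had a median of 0.07 (13 of 18 higher, percentile 51.7), with Idi1 at 29.4 and 42.4 CPM, interferon genes one of 0.11 (percentile 53.5) and MHC class I genes one of -0.12 (percentile 5.63). Heat shock genes (0.45) and respiratory chain genes (0.47) were higher, as in neurons. So were lists chosen for neurons, with medians of 0.39 for axon injury (13 of 15 higher, percentile 99.99), 0.22 for microtubule (24 of 29, 100) and 0.12 for glutamatergic genes (21 of 30, 99.7). Their members are not all particular to neurons: Mapt, in the microtubule list, had a higher level in these nuclei than in granule-like neurons. Oligodendrocyte-like nuclei had median mitochondrial shares of 0.306% and 0.450%, and genes under 5 kb had a median of 0.25.

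In microglia-like nuclei no list of microglial genes lay outside the central 95% of random lists. The disease associated list had a median of 0.13 (13 of 22 higher, percentile 91.4), with the ferritin gene Fth1 at 340.5 and 502 CPM and the protease gene Ctsb at 343 and 442 CPM. Homeostatic microglia genes had a median of -0.11 (5 of 16 higher, percentile 22.3, or 0.98 with lists matched on gene length), while Tmem119 was at 109 and 161 CPM. MHC class I genes had a median of 0.37 (7 of 12 higher, percentile 95.7), complement genes one of -0.06 (percentile 48.0), with C1qb at 299.6 and 335 CPM, cytokine and chemokine genes one of -0.03 (29.9), lysosome genes one of -0.03 (51.6) and interferon genes one of -0.01 (40.2). MHC class II genes were too low for a median. Tm9sf4 (35.4 against 109 CPM), Atp5l (62.6 against 144 CPM) and Tuba1a (177 against 374 CPM) were higher. The lowest ratios were those of Nrg3 at 362 CPM (303 to 429) and 109.9 CPM (90.4 to 132), Kcnip4 at 455 and 169 CPM and Csmd1 at 392 and 149.6 CPM, which are abundant in neurons. Lists chosen for neurons, whose members are not all particular to them, went both ways in these nuclei, with medians of 0.49 for axon injury (12 of 14 higher, percentile 99.95), 0.19 for microtubule (21 of 29, 99.8), -0.21 for glutamatergic (11 of 30, 0.17), -0.22 for GABAergic (5 of 16, 2.12) and -0.49 for channel genes (5 of 22, 0). Gpr34, a receptor gene of microglia, was at 466 and 370.4 CPM. In these nuclei the median mitochondrial share was 0.242% and 0.314%, genes under 5 kb had a median of 0.18 and genes over 100 kb one of -0.14.

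Across the 59 pairs of list and class chosen beforehand, 19 medians lay above and 6 below the central 95% of random lists matched on expression. Matching on gene length too moved pairs both ways. The p53 list in granule-like and inhibitory neuron-like nuclei and cholesterol synthesis in astrocyte-like nuclei came inside. Homeostatic astrocyte and microglia genes and myelin genes in oligodendrocyte-like nuclei fell below. Heat shock and respiratory chain genes lay above it in 13 of 13 classes and microtubule genes in 12. The heat shock medians reached from 0.23 in newly formed oligodendrocyte-like to 0.59 in fibroblast-like nuclei. The Alzheimer risk and tau list had medians of 0.04 in granule-like neurons (percentile 67.6), 0.08 in CA1-like neurons (94.9), -0.09 in microglia-like (27.0) and 0.10 in oligodendrocyte-like nuclei (95.05). MHC class II genes reached a median only in fibroblast-like nuclei among the classes examined (-0.09, percentile 34.6). Genes under 5 kb were higher in each of the 7 main classes, with medians from 0.16 to 0.25, and genes over 100 kb had medians from -0.14 to -0.0057.

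**Figure D3:**
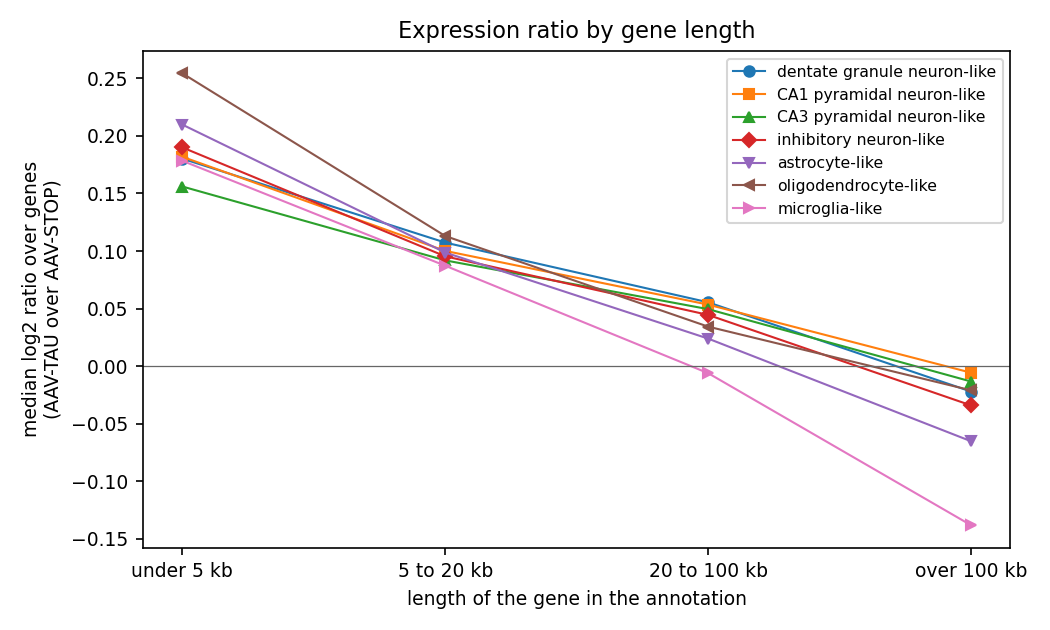
Median log2 ratio (AAV-TAU over AAV-STOP) of all expressed genes, grouped by the length of the gene, in the 7 main classes; each point is the median over the genes of 1 length group in 1 class. Medians decline from the group under 5 kb (0.16 to 0.25) to that over 100 kb (-0.14 to -0.0057).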

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

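Each of the 3 results here is a cluster of no class that held more than 2 times the share of nuclei in AAV-TAU that it held in AAV-STOP; none is weighed for a cause, and the test of the UMI floor cited here was chosen after the result was seen. With 1 library per group, a cluster mostly of 1 library may be that library rather than a cell type, which was not tested for these clusters. The microglia-like share, at a ratio of 3.30, had a log2 value that shrank by 66.0% at a common floor of 2000 UMIs, where a ratio of 1.50 remained. That floor lay near the smallest AAV-STOP barcode, so it removed mainly AAV-TAU nuclei.

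Cluster 14 at resolution 1, led by Gm42418, Lars2, Camk1d, Hpca and Cmss1, held 141 AAV-STOP nuclei (0.799%) and 561 AAV-TAU nuclei (3.23%), a ratio of 4.05, at a median of 1858 UMIs. Cluster 47 at resolution 2, led by Gm42418, Cmss1, Lars2 and Camk1d, held 38 AAV-STOP nuclei (0.215%) and 463 AAV-TAU nuclei (2.67%), a ratio of 12.4, at a median of 1771 UMIs. Both medians lie below 1973, the smallest UMI count of any AAV-STOP barcode, so most of these nuclei had no counterpart of equal depth in that library. Gm42418 over all nuclei stood at 10402 CPM in AAV-STOP and at 13748 CPM in AAV-TAU.

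Cluster 48 at resolution 2, led by Syt9, Ano1, Nwd2, Syt6, Ebf1, Kctd8 and Chrna3, held 0 of 17653 AAV-STOP nuclei, which allows a share of up to 0.0170%, and 83 AAV-TAU nuclei (0.479%), at least 28.2-fold higher. Cluster 27 at resolution 1, which also has Ano1 and Syt9 among its leading genes, held 101 AAV-STOP and 140 AAV-TAU nuclei. Cluster 38 at resolution 2, led by Ano1 too, held 101 AAV-STOP and 57 AAV-TAU nuclei. Clusters 38 and 48 together held as many nuclei of each library as cluster 27, with leading genes in common, so they are likely parts of it. Cluster 27 as a whole held 0.572% of AAV-STOP and 0.807% of AAV-TAU nuclei, so the 28.2-fold bound need not mean a population absent from AAV-STOP. Whether the finer clustering parted 1 cell type by library here was not tested.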

How the results depend on the processing

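Floors of 2000 and 2500 UMIs, the mixed cluster of macrophage and microglial genes counted in, another clustering seed, nuclei matched on mitochondrial share, the microglial part of the mixed cluster and the clusters of resolution 2 inside 2 classes were chosen after seeing the data. No paired analysis was possible because each group was 1 library of pooled mice. Of 3632 recomputed log2 ratios of 260 gene values, 3394 stayed within the counting error of the reported counts, 223 moved beyond it and 15, of genes whose interval excluded no difference, changed sign. Nuclei thinned to 1000 UMIs gave 80 of the 223 and 10 of the 15. Their own counting error is wider, since fewer counts are left. Of 939 list medians 876 moved by no more than a tolerance, 58 moved by more and 5, of lists outside the central 95% of random lists, changed sign. The tolerance was the distance from the middle to the edge of that central range, from 0.035 to 0.373 over 59 medians. It was 0.21 for reactive astrocyte genes, whose move from -0.30 to -0.11 over all members with a UMI lay within it, and 0.047 for microtubule genes in granule-like neurons. Of 167 log2 share ratios 147 stayed within their 95% binomial intervals and 20 did not. Values with no such difference changed sign as well: 37 medians of 11 pairs of list and class, 38 ratios of 22 pairs of gene and class and 18 share ratios of 5 classes, nuclei of no class among them, counted above as stayed or moved. A floor of 1000 UMIs moved nothing, since every nucleus passes it, so it tests nothing. At a floor of 2000 UMIs 6 share ratios moved beyond their intervals and 10 did not. That of microglia-like nuclei moved most, while that of CA3-like neurons moved more with resolution. Reported log2 share ratios were -0.18 for CA1-like, -0.01 for CA3-like, -0.29 for granule-like, 0.07 for inhibitory, 1.72 for microglia-like and 0.36 for oligodendrocyte-like nuclei. At 2000 UMIs they were -0.047 for CA1-like, -0.16 for granule-like, 0.20 for inhibitory, 0.59 for microglia-like and 0.15 for oligodendrocyte-like nuclei. At 2500 UMIs they were -0.027 for CA1-like, 0.14 for CA3-like, -0.15 for granule-like, 0.22 for inhibitory, 0.31 for microglia-like and 0.11 for oligodendrocyte-like nuclei. CA1-like neurons stood at -0.30 with marked doublets kept, at resolution 0.5 (-0.30) and with genes centred (-0.30). CA3-like neurons stood at 0.18 at resolution 0.5 and at 0.21 at resolution 2. With the mixed cluster of macrophage and microglial genes counted in, the microglia-like value was 0.33. In granule-like neurons, median of ratios scaling gave 0.18 for the axon injury list, 0.097 for the microtubule list, -0.14 for the unfolded protein list, 0.37 for heat shock and 0.24 for the respiratory chain. It set the median of all granule-like genes at -0.0081 in place of 0.07, which lowers each list by construction. The axon injury list was at 0.16 over all members with a UMI, the microtubule list at 0.21 with a pseudocount of 1 and at 0.21 as a mean over nuclei, and the respiratory chain at 0.25 with nuclei matched on mitochondrial share. The unfolded protein list turned to 0.0077 (mean over nuclei) and 0.00057 (all members with a UMI) in CA1-like neurons and to 0.036 in CA3-like neurons (resolution 0.5). Thinning to 1000 UMIs turned the microtubule list in CA3-like neurons to -0.061 and the disease associated oligodendrocyte list to 0.0017. It also turned Stat2 in CA1-like neurons to -0.12, Nefm, Gabrg3 and Gabbr1 in CA3-like neurons to -0.17, 0.032 and -0.11, Tnc in astrocyte-like nuclei to 0.0021 and Homer1 in granule-like neurons to 0.013. In inhibitory neuron-like nuclei it turned Jun, Pdia4, Bax and Stat2 to -0.092, 0.084, -0.040 and -0.28. In CA3-like neurons Arhgap6 turned to 0.17 at resolution 0.5, 0.93 at resolution 2 and 0.067 without the response-list genes, and Gabrg3 to 0.31 and 0.26 at resolutions 0.5 and 2. Thinned sums hold fewer counts. Means over nuclei, which also give each nucleus equal weight but keep all counts, turned neither of the 2 lists and none of the genes that thinning turned. Equal weight per nucleus therefore did not by itself give those turns. Every nucleus held over 1000 UMIs, so thinned sums and means over nuclei differ only by the draw of counts. The turns under thinning therefore came from that draw and not from depth. Except for the scaling and these turns, the cause of the other changes was not tested.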

Other observations

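The tests of explanations here were set after the patterns had been seen in an earlier computation of the same data. Those of the common UMI floor, of marked barcodes kept, of matched fibroblast-like nuclei and of the glucocorticoid list in the oligodendrocyte lineage at resolution 2, in precursor-like and in newly formed oligodendrocyte-like nuclei were chosen after the result was seen, and so were the 20 repeated draws of nuclei matched on mitochondrial share; the lists of glucocorticoid-induced and clock genes were written after Zbtb16 had been seen. The pairs of list and class in this part, and the genes Hmgcs1, Fdps, Fdft1 and Idi1 in neurons, Zbtb16 outside the oligodendrocyte lineage, Fkbp5, Tsc22d3 and Errfi1, were chosen after their values were seen.

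Genes of cholesterol synthesis were higher in AAV-TAU in granule-like and CA1-like neurons. In granule-like neurons 14 of 16 measured members were higher, with a median log2 ratio of 0.23 at percentile 99.99. Hmgcs1, an early enzyme of the pathway, was at 17.4 and 26.4 CPM, Fdps at 11.6 and 16.9 CPM and Fdft1 at 15.5 and 21.7 CPM. In CA1-like neurons 16 of 16 were higher (median 0.24, percentile 100), with Idi1 at 6.75 and 10.7 CPM. Random lists matched on gene length too put both medians at percentile 100. Myelin genes (medians 0.23 and 0.19) and mitochondrial shares (0.169% against 0.268% and 0.119% against 0.216%) were higher in these classes as well. The median was 0.29 in oligodendrocyte precursor-like nuclei (12 of 16 higher, percentile 99.1) and 0.15 in immature neuron-like nuclei (12 of 18 higher, percentile 87.2). It was 0.10 in CA3-like neurons (percentile 69.6), 0.07 in inhibitory neuron-like nuclei (50.1) and -0.28 in fibroblast-like nuclei (6 of 17 higher, percentile 0.37), a class drawn from clusters 25 and 32 in unlike parts.

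Immature neuron-like nuclei had Sox2ot, a long non-coding RNA, at 100.1 and 341 CPM, the transcription factor gene Meis2 at 93.7 and 192 CPM and the adhesion gene Nrxn3 at 533 and 1226 CPM. The growth factor receptor gene Egfr was at 71.2 and 28.7 CPM in them.

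Heat shock and respiratory chain genes were higher in AAV-TAU in each of the 13 classes, and granule-like neurons were used to weigh why. A shift of short genes against long ones is argued against as the whole account: the lower of both list percentiles among lists matched on expression and gene length was 100. RNA from outside the nucleus, more of it in the AAV-TAU library, remains a candidate explanation: inside AAV-STOP alone, granule-like nuclei in the top quartile of mitochondrial share exceeded those in the lowest by 54.9% of the difference between the libraries in the heat shock list and by 103% in the respiratory chain list. Inside AAV-TAU the same contrast was smaller, with log2 values of 0.11 and 0.19 against 0.25 and 0.33 inside AAV-STOP. The AAV-STOP quartile limits of 0.098% and 0.298% also lay further apart than the granule-like medians of 0.169% and 0.268%. The percentages can therefore exceed what the library difference could carry. How much the mitochondrial share accounts for cannot be told apart from the group, since over 20 draws matching granule-like nuclei on it kept 87.3% to 97.1% of the heat shock median and 74.5% to 89.1% of the respiratory chain median, while the respective ranges were 60.3% to 76.7% and 49.8% to 72.9% in CA3-like neurons and 82.1% to 100.2% and 83.5% to 99.6% in astrocyte-like nuclei. Fibroblast-like nuclei had the largest medians of both lists (0.59 and 0.50), although their mitochondrial share was not higher in AAV-TAU (0.387% and 0.372%). Matching kept 73.1% to 116.6% there, but with no higher AAV-TAU share to take out it could not test that explanation. The class was also drawn from clusters 25 and 32 in unlike parts. A response of the cells to tau stays open and untested, since 1 library per group ties tau to every difference in preparation.

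The larger microglia-like share in AAV-TAU went with a lower floor of UMIs in that library, which could set part of it. With a common floor of 2000 UMIs the log2 ratio of shares shrank by 66.0%, to 0.59. That floor lay near the smallest AAV-STOP barcode (1973 UMIs), and it left 140 AAV-STOP and 188 AAV-TAU nuclei of the class. A fall was therefore largely built in. AAV-TAU nuclei of the class were also shallower, with a median of 1925 UMIs against 2210. The size of the fall thus cannot part a lower barcode floor from lower depth. With marked barcodes kept the log2 ratio of shares was 1.62 (95% binomial interval 1.37 to 1.88), 94.0% of the reported value. That value cannot decide on doublet marking, since the class changed little, from 156 to 170 AAV-STOP and from 506 to 505 AAV-TAU nuclei. With mixed microglial barcodes counted, marking took out 29.1% in AAV-STOP and 34.7% in AAV-TAU, which lowers the AAV-TAU share. In that wider set this argues against doublet marking as the source of the larger share. At 2500 or more UMIs marking took out 36.1% in AAV-STOP and 77.1% in AAV-TAU. The turned direction of the wider set at a common floor, seen without marked barcodes, may therefore come partly from the marking. With mixed barcodes of microglial type counted too, the ratio with marked barcodes kept was 1.598, or 1.10 at 2000 and 0.970 at 2500 or more UMIs. A larger number of microglia in tissue that expresses tau stays open and untested.

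Zbtb16 was lower in AAV-TAU across the oligodendrocyte lineage, and its log2 ratio was -1.12 in fibroblast-like, -0.64 in astrocyte-like, -0.16 in granule-like, 0.64 in microglia-like and 0.73 in immature neuron-like nuclei. Zbtb16 is induced by glucocorticoids, and the other glucocorticoid-induced genes in oligodendrocyte-like nuclei had a median of -0.12 (5 of 15 higher) at percentile 0.500, with Fkbp5 at 99.1 and 67.0 CPM, Tsc22d3 at 256 and 200.1 CPM and Errfi1 at 104 and 84.1 CPM. Lower signalling of their receptor in the AAV-TAU pool at collection cannot be told apart in the lineage, since that median was -0.25 to 0.12 inside the 3 oligodendrocyte-like clusters of resolution 2, 0.16 in precursor-like (8 of 11 higher, percentile 82.6; -0.07 to 0.24 over resampled members) and -0.13 in newly formed oligodendrocyte-like nuclei (2 of 10 higher, percentile 4.77; -0.26 to 0.13). Elsewhere it was -0.28 in microglia-like (percentile 1.75), -0.12 in astrocyte-like (4.77) and -0.16 in fibroblast-like nuclei (10.8), the last with Fkbp5 at 783 and 330.1 CPM, but 0.09 in granule-like (69.7), 0.17 in inhibitory (94.5), 0.16 in CA1-like (98.2) and 0.17 in CA3-like neurons (98.0). The last pair lay just above the limits of random lists (0.154 and 0.168), which were not matched on gene length. Short genes were higher in AAV-TAU in both classes, so the pair cannot decide on lower signalling in the whole pool. Another time of day at collection cannot be told apart, since the medians of clock genes of opposite phase differed by -0.10, with a spread of 0.111 over resampled genes, and an effect of tau stays open and untested.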
